A study of Homo sapiens with 8 samples.

How the data were processed

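RNA sequencing of 2 human prostate cancer cell lines, DU145 and PC3, was analysed from 1 deposited gene table. Per the labels' protocols, the cells were grown at 37 °C in 5% CO2 and received a lentivirus that carries TRIB1 or an empty lentivirus as the control, total RNA was taken up in TRIzol, and libraries were made with an NEB Ultra RNA kit. The 8 libraries form 4 groups of 2: DU145 control, DU145 TRIB1, PC3 control and PC3 TRIB1. Group and replicate number were read from the sample titles. The labels do not say whether replicates were separate cultures or separate infections, so p-values measure only the spread between these libraries, which may be technical.

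The deposited table holds 57905 genes and 8 columns of per-sample values in TPM (transcript values scaled to the same total in every library), and each column sums to 1000000, per the file itself. The submitters' processing notes name TopHat2 2.0.14, HTSeq, DESeq, edgeR and the build hg38, but which tool made the TPM values, the gene annotation, the strand setting and the gene lengths used are not given in the sources used here. TPM keeps no library totals, so the depth of each library is unknown and no counting interval was computed. A value of 0 is reported only as listed at 0. Because the deposited values are shares of a fixed total, a gene group that takes up more of the RNA lowers the values of all others. The intervals in the table are printed as listed. Of 52338 gene identifiers shared with GENCODE 29 on GRCh38, 365 (0.7%) have the same start, so the listed intervals are not those of the build in the notes and their own build is not stated. No coordinate was converted. Symbols were brought up to date through the gene identifier for 51996 genes. Of 29 symbols that a spreadsheet had turned into dates, 28 were restored from the identifier, and 2300 identifiers share a symbol with another. COP1 is listed under the older name RFWD2 and CXCL8 under IL8. Values of close paralogs (ALPP and ALPG, SAA2 and its neighbour SAA1, the MT1 family, CXCL1 with CXCL2 and CXCL3) and of gene models that overlap (KRT8 and KRT18) are uncertain, because reads may have been shared between them, and genes with an antisense partner cannot be told from it without a strand setting.

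The test of each gene was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(TPM + 1), so a log2 change understates the change of a low gene. Genes with a mean of at least 1 TPM in any group were kept, 25982 in all. All 8 libraries entered 1 fit with 4 group means, which leaves 4 residual degrees of freedom (prior degrees of freedom 1.89), and adjusted p-values are Benjamini-Hochberg values over the genes tested. A gene was called at an adjusted p below 0.05 and an absolute log2 change over 1, the cutoff stated in the series' design. The words rose and fell are used at an adjusted p below 0.05 alone, and called adds the fold. The contrasts were TRIB1 against control in each line, the difference of these changes (DU145 minus PC3), and control PC3 against control DU145. The design fixed in advance assumed a count table with a quasi-likelihood count test. The table holds TPM, to which no count test applies, so the limma test named there for normalized values was used.

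Before the data were examined, 43 lists of 883 genes were fixed (pathways, differentiation states and markers of other cell types). The 40 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists, beside camera with an estimated correlation and the directional test fry. The lists of neuroendocrine, endothelial and lymphocyte genes had 4, 4 and 3 measured members and were not tested. Members are counted over all genes tested and adjusted over the list alone. The rule for named genes was also fixed before. It takes TRIB1 first. For each line it takes the 8 largest called changes per direction with a symbol, at least 5 TPM in a group and both TRIB1 libraries on 1 side of both controls. COP1, CEBPA, CEBPB, NFKBIZ, CXCL2, CXCL8 and IL6 are always reported. It further takes the 4 members with the smallest p of each list past the camera test, the 10 called genes shared by both lines in 1 direction with the largest smaller change, the 8 called differences between the lines with the smallest p, and the 6 largest differences per direction between the controls. Genes outside this rule, among them the largest protein-coding changes that stand in for short RNAs, were chosen after their values were seen. 1 gene picked by the rule for the controls is not reported here.

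The procedure was tested on simulated data. With 200 of the 25982 genes changed, it called 83% of those changed by a log2 of 1.5 and 96% of those changed by 3 in DU145, with 13 of 25782 unchanged genes called. In PC3 it called 89% and 95%, with 6 unchanged genes. The changed genes were drawn from those over 5 TPM in the control of the line, and simulated falls stopped at 0 TPM. The share called among changed genes between 1 and 5 TPM is therefore not shown. A shift of 0.5 in the mitosis list alone in DU145 was called, and 0 of the other lists were. The simulated noise was independent between genes, whereas the estimated correlation of the mitosis list in the data was 0.239. The simulation therefore does not show how camera at the preset correlation behaves when members of a list vary together. Alternatives planned in advance were a pseudocount of 0.1, no filter, no fold cutoff, a replicate block, the 4 libraries of a comparison alone, each library left out in turn, and the other list tests. Alternatives added after the data were seen were median-of-ratios and upper-quartile scaling, a filter of 5 TPM in 2 libraries, limma treat against a fold of 1.2, no trend, protein-coding genes alone, and TPM recomputed over them. The former scaling moves the median difference between the controls by 0.187 on the log2 scale and upper-quartile scaling by 0.163. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.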

Results

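Transcript levels were measured by RNA sequencing in DU145 and PC3, established lines grown from a brain and a bone metastasis of prostate cancer, after a lentivirus had added TRIB1 or nothing. TRIB1 encodes a pseudokinase that brings substrates such as C/EBP transcription factors to the ubiquitin ligase COP1. The comparison in each line asks which transcripts differ when TRIB1 is raised. Each of the 4 groups holds 2 libraries. The depth of the libraries is unknown, since TPM values keep no totals. Between 30398 and 31694 genes were above 0 and between 19731 and 21335 reached 1 TPM per library. The first principal component of the 2000 most variable genes held 71.6% of their variance and separated the lines. The second held 10.3% and set apart the second DU145 TRIB1 library, at -61.7 against 21.5 to 24.9 for the other DU145 libraries. In that library RN7SL1 and RN7SL2, abundant short RNAs of the signal recognition particle, took 3.17% of all TPM, against 1.266% to 2.239% in the other 7.

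TRIB1 (ENSG00000173334, chromosome 8, 126442563 to 126450647) was first read in each library by itself. In DU145 it stood at 10.1 and 7.94 TPM in the controls and at 69.4 and 62.3 TPM in the TRIB1 libraries. In PC3 it stood at 45.1 and 50.8 TPM in the controls and at 241 and 245 TPM in the TRIB1 libraries. TRIB1 therefore rose from 9.0 ± 1.5 to 65.9 ± 5.05 TPM in DU145 (SD, n = 2 each; log2 change 2.75, SE 0.12, adjusted p = 0.0018) and from 48.0 ± 3.99 to 243 ± 2.52 TPM in PC3 (log2 change 2.32, SE 0.12, adjusted p = 0.00095). The difference between the 2 changes, 0.43, did not pass the test (adjusted p = 0.192). Control PC3 held more TRIB1 transcript than control DU145 (log2 difference 2.30). COP1 did not pass in either line (log2 change -0.19, adjusted p = 0.68 in DU145; -0.21, adjusted p = 0.542 in PC3), and neither did CEBPA (-0.45, adjusted p = 0.351; -0.68, adjusted p = 0.0852).

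**Figure D1:**
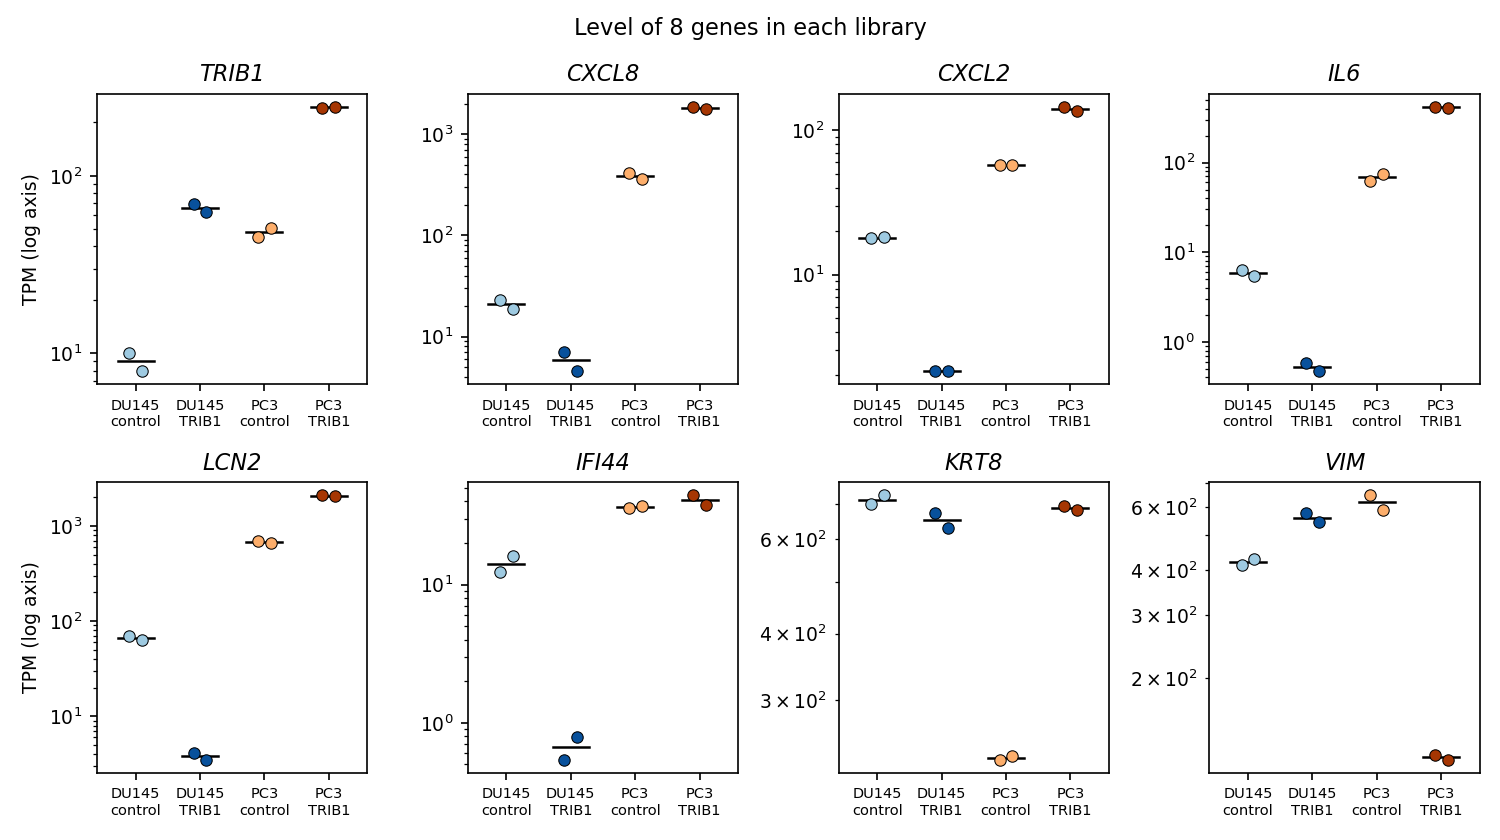
TPM (log axis) of TRIB1, CXCL8, CXCL2, IL6, LCN2, IFI44, KRT8 and VIM in each of the 8 libraries; points are libraries and bars are the means of 2. TRIB1 is higher with TRIB1 virus in both lines, whereas CXCL8, CXCL2, IL6 and LCN2 are lower in DU145 and higher in PC3.

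In DU145, the largest called falls under the rule included PDZK1IP1, LCN2, SAA2 and C3. LCN2 (ENSG00000148346, chromosome 9, 130911350 to 130915412), which encodes a siderophore-binding protein of innate immunity, fell from 66.0 ± 4.59 to 3.81 ± 0.415 TPM (SD, n = 2 each; log2 change -3.80, SE 0.08, adjusted p = 0.000218). PDZK1IP1, a small membrane protein gene, fell from 77.2 ± 9.10 to 4.59 ± 1.28 TPM (log2 change -3.82, adjusted p = 0.00424). The acute phase gene SAA2 fell from 29.7 ± 4.20 to 2.06 ± 1.60 TPM (log2 change -3.43, adjusted p = 0.0128) and the complement gene C3 from 32.1 ± 13 to 2.11 ± 0.906 TPM (log2 change -3.39, adjusted p = 0.0132). SLPI, a protease inhibitor of mucosal fluids chosen after its values were seen, fell from 81.9 ± 10.1 to 9.19 ± 1.08 TPM (log2 change -3.02, adjusted p = 0.0018). SAA2 lost its call without either DU145 control or either PC3 TRIB1 library (adjusted p 0.059 to 0.0795), and C3 without the first DU145 TRIB1 library or either PC3 TRIB1 library (adjusted p 0.0514 to 0.0521).

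Other genes rose in DU145. The zinc finger gene ZNF595 rose from 2.21 ± 0.960 to 19.3 ± 0.113 TPM (log2 change 2.70, adjusted p = 0.0121), a call that ended without either DU145 TRIB1 library (adjusted p 0.0534 and 0.0606). Of protein-coding genes chosen after their values were seen, SYNE1, a nuclear envelope protein gene, rose from 11.1 ± 1.27 to 59.2 ± 1.74 TPM (log2 change 2.32, adjusted p = 0.00528). The folate receptor gene FOLR1 rose from 2.50 ± 0.641 to 14.3 ± 0.344 TPM (log2 change 2.14, adjusted p = 0.00695), and TNNC1, a troponin gene, from 44.1 ± 1.01 to 178 ± 16.8 TPM (log2 change 1.98, adjusted p = 0.00424). The rule for named genes otherwise gave pseudogenes, short RNAs and clone-named genes. RPS29P31, MIR1273A, RP11-1012A1.10, RNA5SP229, AC004076.7 and RNU6-242P were called higher, with log2 changes of 2.71 to 3.28. RNU1-72P, RNU2-18P, RP11-599B13.6 and RP11-804F13.2 were called lower, with log2 changes of -4.26 to -3.35. The calls of RPS29P31, MIR1273A, RNU1-72P, RNU2-18P and RP11-804F13.2 each ended without at least 6 single libraries, with adjusted p up to 0.206.

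In all, 290 genes were called in DU145, 81 higher and 209 lower, of which 193 are protein-coding (39 higher and 154 lower). With the 4 DU145 libraries fitted alone 46 were called, 9 higher and 37 lower. In the fit of all 8 libraries, 707 genes had an adjusted p below 0.05 whatever their fold. The count depended on single libraries: it was 436 (65 higher and 371 lower) without the first DU145 control, 510 (68 and 442) without the second, 584 (405 and 179) without the first DU145 TRIB1 library and 454 (276 and 178) without the second. Without the first or second PC3 TRIB1 library it was 195 (60 and 135) or 196 (60 and 136), and with treat 52 genes were called higher. Between 150 and 231 of the 290 genes stayed called in the same direction with 1 library left out.

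Of the gene lists, interferon-stimulated genes, which respond to viral RNA and interferon, had the smallest camera p in DU145. Of 37 measured members 19 fell, 0 rose and 18 did not pass (29 fell when adjusted over the list alone). The median log2 change was -0.89 (camera adjusted p = 1.703e-22; adjusted p = 0.0338 with an estimated correlation). IFI44 (ENSG00000137965, chromosome 1, 79115481 to 79128441) fell from 14.2 ± 2.65 to 0.663 ± 0.170 TPM (log2 change -3.19, adjusted p = 0.00259). The RNA sensor gene IFIH1 fell by 1.87, IFI6 by 1.53 and the viral entry inhibitor gene IFITM3 by 1.33 on the log2 scale. The count of 19 was 11 or 12 without either DU145 control, the first DU145 TRIB1 library or either PC3 TRIB1 library. Of 20 antigen presentation genes 10 fell and 0 rose (16 fell when adjusted over the list alone), with a median of -0.72 (camera adjusted p = 6.152e-10; adjusted p = 0.174 with an estimated correlation). PSMB9, an immunoproteasome gene, fell from 175 ± 0.902 to 83.6 ± 8.39 TPM, and HLA-B from 505 ± 34 to 279 ± 14 TPM. HLA-E fell by 0.69 and PSMB8 by 0.67 on the log2 scale. Each of these 4 genes lost its adjusted p without 2 or 4 of the single libraries (up to 0.0743). Here the count of 10 was 0 and 3 without the first and second DU145 control, 4 without the second DU145 TRIB1 library, 1 without either PC3 TRIB1 library, 4 after upper-quartile scaling and 16 with protein-coding genes alone.

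NF-kB targets were lower in DU145 as well. Of 20 cytokine and chemokine genes 11 fell and 0 rose (14 fell when adjusted over the list alone), with a median log2 change of -1.05 (camera adjusted p = 2.792e-11; adjusted p = 0.174 with an estimated correlation). The neutrophil attractant genes CXCL1 and CXCL2 fell from 27.1 ± 5.27 to 3.02 ± 0.093 TPM and from 18.0 ± 0.117 to 2.15 TPM (log2 changes -2.79 and -2.60, adjusted p = 0.0018 and 0.000351). IL6 (ENSG00000136244, chromosome 7, 22765503 to 22771621) fell from 5.87 ± 0.684 to 0.527 ± 0.078 TPM (log2 change -2.17, adjusted p = 0.00282). CXCL8 (ENSG00000169429, chromosome 4, 74606223 to 74609433) fell from 20.95 ± 2.88 to 5.85 ± 1.81 TPM (log2 change -1.70, adjusted p = 0.0169). That call ended without the first or second DU145 control (adjusted p = 0.0925 and 0.0607) and without either PC3 TRIB1 library (0.0711 and 0.0705). CSF1, a macrophage growth factor gene, fell from 60.4 ± 3.15 to 22 ± 3.03 TPM. The list count of 11 was 7 without the first DU145 control or either PC3 TRIB1 library. Of 21 NF-kB feedback and signalling genes 9 fell and 0 rose (16 fell when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 3.707e-15; adjusted p = 0.23 with an estimated correlation), and with protein-coding genes alone 15 fell. ICAM1, an adhesion molecule gene, fell by 1.62, ZC3H12A by 1.57, SOD2 by 1.54 and the apoptosis inhibitor gene BIRC3 by 1.14 on the log2 scale. CEBPB, a C/EBP factor that drives many of these genes, stood at 200 ± 28.3 and 85.2 ± 17.1 TPM and did not pass (log2 change -1.23, adjusted p = 0.0502). NFKBIZ did not pass either (-0.92, adjusted p = 0.122).

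The camera test passed 11 further lists in DU145, and with an estimated correlation none of these 11 did. Higher were genes of the ATF4 stress response (6 of 24 rose, 0 fell; 12 and 2 when adjusted over the list alone; median 0.27, adjusted p = 0.321 with an estimated correlation), with the serine synthesis genes PSAT1 at a log2 change of 0.66 and PHGDH at 0.60, the amino acid transporter gene SLC7A5 at 0.92 and MTHFD2 at 0.59. Each of these 4 lost its adjusted p without 5 or 6 of the libraries, up to 0.183. Cytosolic ribosomal proteins (0 of 53 rose or fell, 3 rose when adjusted over the list alone; median 0.10, but 0.04 without the first DU145 TRIB1 library and 0.17 after median-of-ratios scaling; adjusted p = 0.512), mitosis genes (0 of 30 rose, 1 fell; 2 and 1; median 0.09, adjusted p = 0.524) and heat shock genes (0 of 18 either way, 0 over the list alone; median 0.13, adjusted p = 0.512) were also higher as lists, each adjusted p being that with an estimated correlation. Lower were metallothioneins, which bind zinc and copper (1 of 7 fell, MT2A from 692 ± 16.2 to 379 ± 0.100 TPM; 5 when adjusted over the list alone; median -0.42). Hypoxia genes were lower too (4 of 25 fell, 0 rose; 8 and 1 over the list alone; median -0.26), with the angiogenesis gene VEGFA at -1.41 and the collagen crosslinking gene LOX at -1.21, as were collagens and laminins (5 of 24 fell; 7 and 1 over the list alone; median -0.22, and -0.14 after median-of-ratios scaling), with LAMA3 going from 18.7 to 8.79 TPM. VEGFA and LOX lost their calls without 6 and 8 of the single libraries (adjusted p up to 0.0877 and 0.14), and the 4 hypoxia genes became 0 to 2 with any of the libraries left out, 2 or 1 after median-of-ratios or upper-quartile scaling and 7 with protein-coding genes alone. The last 4 were stem cell associated genes (3 of 9 fell; 4 over the list alone; ITGA2 -1.17), basal keratins and squamous genes (3 of 15; 5; S100A9 -1.85), BCL2 family genes (1 of 16; 4; BCL2A1 -1.19, a call lost without any 1 of 6 libraries, adjusted p 0.0551 to 0.116) and lysosome genes (2 of 23; 3 and 1 higher; CTSB -0.81). With an estimated correlation the adjusted p of these 7 lower lists was 0.242 to 0.416. Collagens, mitosis, heat shock, stem cell, basal keratin, BCL2 and lysosome lists lost the camera call without at least 1 library (adjusted p 0.0529 to 0.297). Of the 15 lists 4 were higher and 11 lower, and after median-of-ratios scaling 9 were higher and 10 lower.

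In PC3, TRIB1 went with more epithelial and less mesenchymal transcript. KRT8 (ENSG00000170421, chromosome 12, 53290977 to 53343626), a keratin of simple epithelia, rose from 234 ± 2.59 to 686 ± 8.22 TPM (SD, n = 2 each; log2 change 1.54, SE 0.05, adjusted p = 0.000725). The intermediate filament gene of mesenchymal cells, VIM (ENSG00000026025, chromosome 10, 17270258 to 17271949), fell from 618 ± 41.2 to 121 ± 2.53 TPM (log2 change -2.35, SE 0.06, adjusted p = 0.000725). Of 22 epithelial markers 17 rose and 0 fell (20 and 1 when adjusted over the list alone), with a median log2 change of 1.33 (camera adjusted p = 1.198e-16; adjusted p = 0.179 with an estimated correlation). KRT18 rose from 208 ± 12.4 to 595 ± 6.58 TPM, KRT7 from 540 ± 19.2 to 1457 ± 64.4 TPM and the tight junction gene CLDN7 from 52.1 ± 0.626 to 126 ± 3.98 TPM. Among members chosen after their values were seen, the adhesion genes CDH1 and EPCAM rose by log2 changes of 1.53 and 1.78 and the epithelial regulators GRHL2, OVOL1 and ESRP1 by 1.80, 1.81 and 1.51. Of 18 mesenchymal markers 9 fell and 1 rose (14 and 1 when adjusted over the list alone), with a median of -0.59 (camera adjusted p = 2.729e-06; adjusted p = 0.182 with an estimated correlation). The fibrillar collagen gene COL5A1 fell from 34.3 ± 0.052 to 5.23 ± 0.180 TPM, SPARC from 11.9 ± 1.75 to 2.75 ± 0.300 TPM and the matrix protease gene MMP14 from 272 ± 1.43 to 120 ± 6.23 TPM. The count of 9 was 4 without the second PC3 TRIB1 library. Of the same 18 genes, 6 had a higher change in DU145 than in PC3 and 1 a lower one (limma adjusted p below 0.05). The latter was FN1, whose log2 change in DU145 minus that in PC3 was -1.73 (limma adjusted p = 0.00567). Collagens and laminins fell in 17 of 24 cases and rose in 1 (17 and 4 when adjusted over the list alone), with a median of -0.70 (camera adjusted p = 2.729e-06; adjusted p = 0.263 with an estimated correlation). COL6A3 fell from 65.1 ± 2.25 to 11 ± 1.26 TPM, and COL6A2 and LAMA5 fell as well (log2 changes -1.59 and -1.71). The count of 17 was 11 and 8 without the first and second PC3 TRIB1 library.

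Several cytokine and chemokine genes rose in PC3, and others fell. PPBP, a platelet and neutrophil chemokine gene, rose from 1.45 ± 0.302 to 75.5 ± 0.074 TPM (log2 change 4.97, adjusted p = 0.000734). IL6 rose from 68.1 ± 8.04 to 411 ± 11.6 TPM (log2 change 2.58, adjusted p = 0.000761), CXCL8 from 390 ± 37.3 to 1819 ± 58.7 TPM (2.22, adjusted p = 0.0025) and CXCL2 from 57.5 ± 0.198 to 140 ± 7.01 TPM (1.27, adjusted p = 0.00095). Of 20 NF-kB cytokine and chemokine genes 11 rose and 4 fell (12 and 5 when adjusted over the list alone), with a median of 1.24 (camera adjusted p = 0.001085; adjusted p = 0.301 with an estimated correlation). CXCL5 rose from 161 ± 12.8 to 504 ± 0.960 TPM, whereas LIF fell from 195 ± 9.21 to 74.8 ± 3.24 TPM. NFKBIZ fell from 111 ± 8.18 to 54.0 ± 1.97 TPM (log2 change -1.02, adjusted p = 0.0361), a call that ended without any 1 of 6 libraries (adjusted p 0.0661 to 0.166). CEBPB stood at 110 ± 28.8 and 137 ± 2.11 TPM and did not pass (0.33, adjusted p = 0.372). Lists of NF-kB feedback genes (6 of 21 rose, 2 fell), interferon-stimulated genes (6 of 37 rose, 5 fell) and antigen presentation genes (1 of 20 rose, 3 fell) did not pass the camera test in PC3 (adjusted p = 0.166, 0.173 and 0.166). Without a PC3 TRIB1 library 3 NF-kB feedback genes and 2 or 3 interferon-stimulated genes rose. The antigen presentation genes that fell became 0 without a PC3 TRIB1 library or a DU145 control and 1 after upper-quartile scaling.

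Glycolysis and hypoxia genes were lower in PC3 with TRIB1. Of 20 glycolysis genes 16 fell and 1 rose (16 and 1 when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 4.111e-09; adjusted p = 0.182 with an estimated correlation). The enolase gene ENO1 fell from 2638 ± 27.1 to 1462 ± 12.5 TPM, its paralog ENO2 from 95.9 ± 3.63 to 39.8 ± 1.33 TPM, the pyruvate kinase gene PKM from 1894 ± 16.2 to 1052 ± 27.6 TPM and the lactate exporter gene SLC16A3 from 845 ± 133 to 293 ± 1.81 TPM. Of 25 hypoxia genes 14 fell and 1 rose (14 and 1 when adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.464e-06; adjusted p = 0.182 with an estimated correlation). P4HA2, a collagen prolyl hydroxylase gene, fell by 1.56, the carbonic anhydrase gene CA12 by 1.89, PFKFB4 by 1.73 and BNIP3 by 1.14 on the log2 scale. The count of 14 was 9 without the second PC3 TRIB1 library. Cytosolic ribosomal protein genes rose in 32 of 53 cases and fell in 0 (35 and 1 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 3.476e-16; adjusted p = 0.263 with an estimated correlation). RPS20 rose from 668 ± 29.1 to 1352 ± 17.4 TPM and RPL5 from 683 ± 25.3 to 1279 ± 11.3 TPM. The count of 32 was 17 without either DU145 control and 12 and 10 without the first and second PC3 TRIB1 library.

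The camera test passed 11 further lists in PC3, all of them only at the preset correlation (adjusted p 0.182 to 0.595 with an estimated correlation). Higher were the ATF4 stress response (8 of 24 rose, 2 fell; 11 and 3 when adjusted over the list alone; ATF3 1.84, DDIT3 1.18), cholesterol synthesis (9 of 24 rose, 2 fell; 10 and 2; HMGCS1 1.17, STARD4 1.33), YAP and TEAD targets (9 of 18 rose, 3 fell; 10 and 3; ANKRD1 2.66, TGFB2 1.40, but CCN2 -0.79), p53 targets (5 of 20 rose, 1 fell; 7 and 1; the cell cycle inhibitor gene CDKN1A 0.99, PHLDA3 1.34) and basal keratins and squamous genes (7 of 15 rose, 4 fell; 8 and 4; KRT17 2.90, KRT16 1.97, but S100A8 -1.67). Respiratory chain genes (8 of 35 rose, 1 fell; 13 and 1), AKT and FOXO targets (5 of 16 rose, 1 fell; 5 and 1; ERBB3 0.89, TXNIP 0.97) and Notch targets (5 of 11 rose, 1 fell; 5 and 1; JAG2 1.44, but HEY1 -0.97) were also higher, the values after the gene names being log2 changes. Lower were ER chaperones (10 of 24 fell, 1 rose; 11 and 2; PDIA4 -0.71), mitosis genes (11 of 30 fell, 2 rose; 14 and 3) and integrins (5 of 14 fell, 1 rose; 5 and 1; ITGA3 -0.82, ITGB4 -1.16). TXNIP and HEY1 lost their adjusted p without 6 and 1 of the single libraries (up to 0.14 and 0.0563). The AKT, Notch, YAP, basal keratin, integrin, mitosis, p53 and respiratory chain lists lost the camera call without at least 1 library (adjusted p 0.0542 to 0.167), and without the first PC3 control 11 lists passed in place of 18.

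Other large changes in PC3 concerned genes of none of the lists above. IL13RA2, a decoy receptor for IL-13, rose from 1.30 ± 0.307 to 30.004 ± 0.619 TPM (log2 change 3.76, adjusted p = 0.000761). The antiviral cytidine deaminase gene APOBEC3G fell from 55.1 ± 0.766 to 3.79 ± 0.151 TPM (log2 change -3.55, adjusted p = 0.000725) and the secreted mucin gene MUC5AC from 74.9 ± 6.07 to 6.34 ± 0.112 TPM (-3.37, adjusted p = 0.000734). Among genes chosen after their values were seen, SERPINB2 rose from 14.4 ± 3.63 to 133 ± 5.77 TPM, C1orf116 from 6.65 ± 0.301 to 60.4 ± 3.86 TPM and the hair keratin associated gene KRTAP2-3 from 3.54 ± 0.474 to 39.2 ± 0.195 TPM. MSMP, a chemokine-like gene first described in PC3 cells, fell from 3139 ± 269 to 396 ± 5.47 TPM, PDLIM4 from 99.6 ± 8.57 to 12.3 ± 1.75 TPM and the neurotensin receptor gene NTSR1 from 26.9 ± 5.58 to 2.67 ± 0.160 TPM. The rule for named genes also gave AC113342.1, RP11-667M19.10, TRBJ2-2P, AC068533.1, RPS29P19 and AL356776.1 with log2 changes of 3.80 to 5.48. It gave RP11-982M15.2, AC092964.1, AL136137.1, TSPEAR-AS1, CTD-2218G20.1 and AP001062.8 with log2 changes of -3.81 to -3.10. Apart from RP11-667M19.10, TSPEAR-AS1 and CTD-2218G20.1, these genes lost their calls without at least 1 library (adjusted p 0.0524 to 0.16). In all, 1350 genes were called in PC3, 656 higher and 694 lower, 873 of them protein-coding (412 and 461), and 4415 passed on the adjusted p alone. The split was 638 and 960 without the first PC3 control, 697 and 517 without the first PC3 TRIB1 library, 740 and 445 without the second, and 755 and 641 after median-of-ratios scaling, so neither direction prevailed in all settings.

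**Figure D2:**
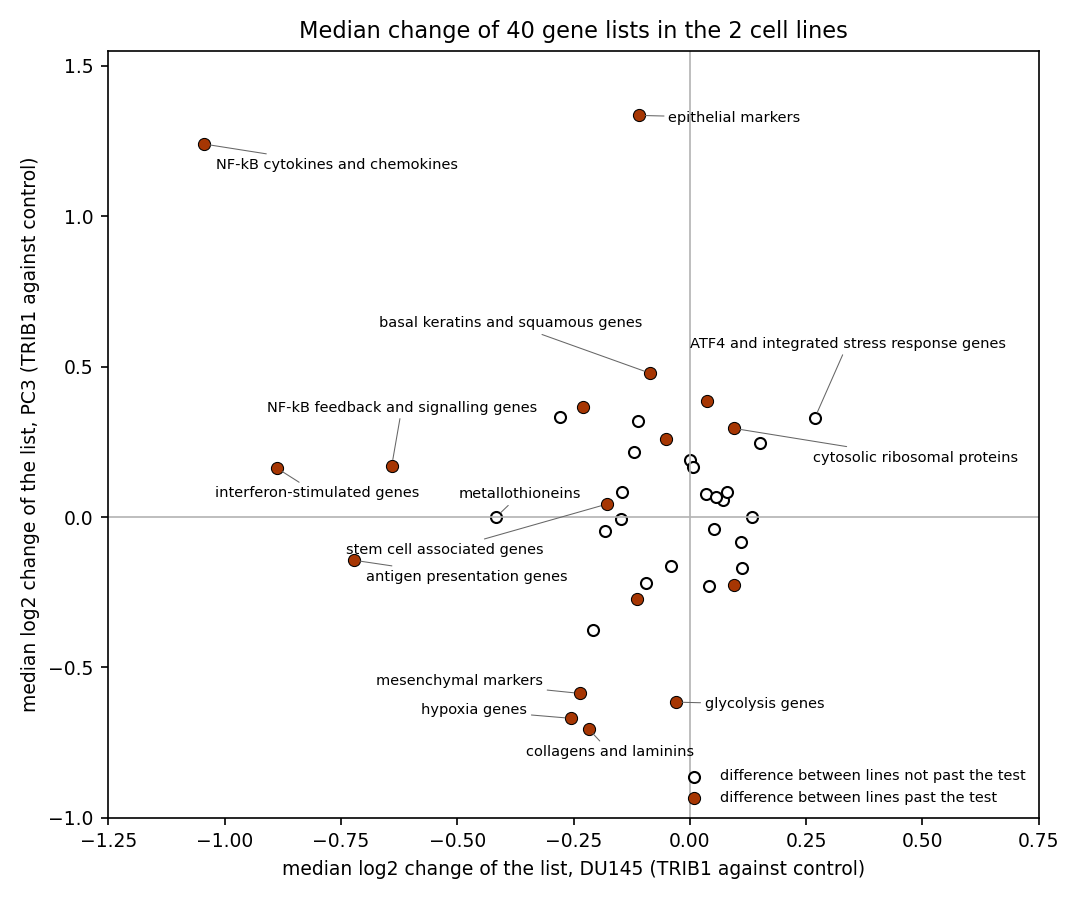
Median log2 change with TRIB1 of the 40 gene lists in DU145 (horizontal axis) and PC3 (vertical axis); each point is a list, and filled points are the 17 lists whose difference between the lines passed the camera test. NF-kB cytokines lie at -1.05 in DU145 and 1.24 in PC3, and epithelial markers at -0.11 (-0.04 without the second DU145 control) and 1.33.

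The changes in the 2 lines differed for many genes. The test of the difference called 1330 genes, 547 with the higher change in DU145 and 783 with the higher change in PC3, of which 990 were protein-coding. The split was 290 and 716 or 303 and 798 without the first or second DU145 control, 345 and 751 or 333 and 787 without the first or second PC3 TRIB1 library, 696 and 654 without the first DU145 TRIB1 library and 841 and 809 without the first PC3 control. The smallest p belonged to LCN2, which fell in DU145 and rose from 682 ± 23.7 to 2071 ± 39.9 TPM in PC3 (difference of log2 changes, DU145 minus PC3, -5.41, adjusted p = 0.000211). CXCL2 (-3.87, adjusted p = 0.000259), VIM (2.75, adjusted p = 0.000834), IL6 (-4.75, adjusted p = 0.000931), SLPI (-4.70, adjusted p = 0.00107), CXCL1 (-4.48, adjusted p = 0.00119), KRT8 (-1.67, adjusted p = 0.00132) and the noncoding RP11-479G22.8 (3.48, adjusted p = 0.00132) followed. CXCL8 differed by -3.92 (adjusted p = 0.00285) and CEBPB by -1.56 (adjusted p = 0.0343), the latter only with all 8 libraries or without the second PC3 control. COP1, CEBPA and NFKBIZ did not differ by the test (adjusted p = 0.975, 0.679 and 0.871). Of the lists, 17 differed, 11 of them lower in DU145 than in PC3. Epithelial markers (16 of 22 members differed, all lower in DU145), interferon-stimulated genes (20 lower and 2 higher of 37) and NF-kB cytokines (12 lower and 2 higher of 20) had camera adjusted p of 1.824e-14, 9.39e-11 and 4.393e-08. With an estimated correlation the lowest adjusted p of any list was 0.116. The 20 interferon-stimulated genes were 12 or 13 without either DU145 control, the second DU145 TRIB1 library or the first PC3 TRIB1 library.

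Some genes moved alike in both lines and others in opposite directions. Called higher in both were 11 genes, against 2.05 for independent sets (one-sided Fisher's exact test, adjusted over 4 overlaps, p = 1.19e-05), and called lower in both were 17, against 5.58 (p = 6.73e-05). NPNT, a basement membrane protein gene, rose from 1.03 ± 0.149 to 5.58 ± 0.314 TPM in DU145 and from 5.28 ± 0.080 to 24.7 ± 0.977 TPM in PC3. IFI6 fell from 277 ± 10.6 to 95.8 ± 15.0 TPM and from 202 ± 2.22 to 64.5 ± 0.701 TPM. The calprotectin gene S100A8 fell by 1.68 and 1.67 on the log2 scale, CLEC2B by 1.46 and 2.06, and TNFRSF6B, a soluble decoy receptor gene on chromosome 20 that is listed at 0 in both DU145 TRIB1 libraries, was called lower in both lines. The noncoding RNU6-260P, RP11-863P13.6 and RP11-503N18.4 were called higher and RN7SL236P lower in both. Lower in DU145 and higher in PC3 were 26 genes, against 5.28 (Fisher's exact test, p = 9.6e-11), among them CXCL1, CXCL2, CXCL3, CXCL8, CCL20, IL6, IL32, TNFAIP3, LCN2, SLPI, PI3, OASL and CDH3. The reverse held for 1 gene, the calcium channel gene ITPR1 (2.16 for independent sets, Fisher's exact test, p = 0.889), chosen after its values were seen. TRIB1 itself is among the 11 genes called higher in both. The calls of both lines came from 1 fit with a shared estimate of the spread of each gene. The sets are therefore not independent, and the Fisher's exact tests may overstate all of these overlaps. With the 4 libraries of each line fitted alone, 46 genes were called in DU145 and 997 in PC3. Of these, 1 was called higher in both lines and 0 lower in both. Fits that share no estimate of the spread thus show no genes called alike beyond that 1, though they call few genes in DU145. Across all 25982 genes, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.006. The 28 genes called alike were 18 (10 higher and 8 lower) without the first PC3 TRIB1 library, 19 (10 and 9) without the second, 21 (10 and 11) after median-of-ratios scaling, 27 (7 and 20) without the second PC3 control and 33 (21 and 12) without the first DU145 TRIB1 library.

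The control libraries give the background on which these changes were measured. Between control PC3 and control DU145, 6610 genes were called, 2542 higher in PC3 and 4068 higher in DU145, 4295 of them protein-coding. After median-of-ratios scaling the split was 3188 and 3091, and after upper-quartile scaling 3132 and 3208. MSMP stood at 3139 ± 269 TPM in PC3 and 1.15 ± 0.301 TPM in DU145 (log2 difference 10.52, adjusted p = 1.8e-06). The trefoil factor gene TFF1 stood at 880 ± 29.6 against 0.311 ± 0.157 TPM, the aminopeptidase gene ANPEP at 769 ± 95.3 against 0.514 ± 0.087 TPM and the cytokine gene IL1B at 769 ± 55.1 against 0.824 ± 0.570 TPM. PI3, an elastase inhibitor gene, and the Wnt receptor gene FZD8 were higher in PC3 by 8.41 and 8.36 on the log2 scale. In the other direction the ubiquitin hydrolase gene UCHL1 stood at 1071 ± 3.63 TPM in DU145 and 0.598 ± 0.011 TPM in PC3 (log2 difference -9.39, adjusted p = 1.03e-05). CAVIN1, a gene of caveolae, stood at 239 ± 2.92 against 0.088 ± 0.006 TPM, and PLPP2 at 167 ± 1.89 against 0.037 ± 0.052 TPM. MT1L and MT1A, closely related metallothionein genes, stood at 351 ± 39.3 and 165 ± 7.58 TPM in DU145 and are listed at 0 in both PC3 controls. CXCL8 and IL6 were higher in control PC3 than in control DU145 by 4.16 and 3.33 on the log2 scale.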

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

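The tests of swapped labels and of admixed DU145 cells were chosen only after the results they bear on had been seen.

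Each result in this part stands out because the effect of TRIB1 differed between DU145 and PC3 in the limma or camera test of the difference itself. This held for 1330 genes. Of the genes reported whatever their values, CEBPB differed by -1.56, CXCL2 by -3.87, CXCL8 by -3.92 and IL6 by -4.75 (log2 change in DU145 minus log2 change in PC3). Among the others with the smallest p, LCN2 differed by -5.41, SLPI by -4.70, CXCL1 by -4.48, KRT8 by -1.67, VIM by 2.75 and RP11-479G22.8 by 3.48. Another 85 of 169 genes named for a line differed as well. Most had been named for a large change or a small p in a line from the same libraries, so the choice itself raises this share. Of all 25982 genes tested, 1330 differed. The median difference over the members was -1.47 for NF-kB cytokines, -1.42 for epithelial markers, -1.12 for basal keratins, -1.10 for interferon-stimulated genes, -0.85 for NF-kB feedback genes, -0.76 for stem cell associated genes, -0.55 for AKT and FOXO targets, -0.51 for YAP targets, -0.50 for antigen presentation genes, -0.27 for cholesterol synthesis genes and -0.22 for ribosomal proteins (-0.135 without the second PC3 control). It was 0.71 for collagens and laminins, 0.49 for glycolysis genes, 0.42 for mesenchymal markers, 0.30 for hypoxia genes (0.11 without the second PC3 TRIB1 library), 0.27 for mitosis genes and 0.18 for ER chaperones. With an estimated correlation 0 of these lists passed (lowest adjusted p = 0.116). The AKT list lost its call without the first PC3 control (adjusted p = 0.0809), the ER chaperone list without any 1 of 3 libraries (0.0549 to 0.172) and the YAP list without any 1 of 4 (0.0612 to 0.173).

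NF-kB cytokine genes were lower in DU145 and higher in PC3. Swapped control and TRIB1 labels in a line are argued against by TRIB1 itself, whose smaller log2 change of the 2 lines was 2.321. Scaling is argued against too, since after median-of-ratios scaling the list median was -0.968 in DU145 and 1.298 in PC3. White blood cells in the cultures are left open by the test set in advance. The highest value of PTPRC, TYROBP and FCER1G in any library was 3.906 TPM, neither under 1 nor at 5 TPM or more. CD68 moved with the pattern (28.9 to 7.12 TPM in DU145, 19.2 to 31.5 TPM in PC3). So did MSR1, at most 1.891 TPM, and TYROBP, whose control and TRIB1 libraries overlapped in both lines. FCER1G did not fall in DU145, and C1QB was listed at 0 in every library. PTPRC never exceeded 0.467 TPM, CD14 1.18 TPM or LYZ 2.07 TPM, and none of these 3 followed the pattern. A response to TRIB1 that depends on the line therefore stays a hypothesis, as does a difference between infected cultures that has nothing to do with TRIB1, which the labels do not allow to be tested.

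Epithelial genes were higher in PC3 with TRIB1. DU145 cells mixed into these cultures are argued against, because 26 genes abundant in DU145 and near 0 in control PC3 gained a median of 0.027% (at most 40.46%) of their DU145 level, while the epithelial genes would need at least 57.4% and 9 of the 16 called ones already lay above the DU145 level in control PC3. Scaling is argued against by a list median of 1.392 after median-of-ratios scaling. Extra copies of the epithelial genes themselves are argued against as the source of the whole pattern. Of the called epithelial genes, 0% lay in the 10 Mb windows whose genes shifted upward together. The test does not reach a subclone in another state, which would not need these genes to lie in such windows. In PC3, 18 windows shifted upward and 4 downward beyond the shuffles, so a subclone stays open. A change of state of the PC3 cells may underlie the pattern, as a hypothesis found and tested on the same data. Whether TRIB1 or the selection of infected cells brought it about was not tested.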

How the results depend on the processing

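The settings of scaling, the 5 TPM filter, treat, no trend and protein-coding genes were chosen only after the data had been seen, and the rest were planned before the data were examined. In every setting in which its own change was read TRIB1 stayed called in both lines (log2 change 2.59 to 2.90 in DU145 and 2.24 to 2.40 in PC3 with 1 library left out), and no called gene or list changed direction. Scaling, pseudocount, filter, trend and treat settings moved no total of called genes by more than 1.5 times, but with treat the genes higher in DU145 went from 81 to 52, and with median-of-ratios scaling the genes lower in both lines from 17 to 11. Without the fold cutoff the counts were 707 in DU145, 4415 in PC3, 2434 for the difference, 12216 for the controls and 173 for genes alike in both lines. Testing protein-coding genes alone gave 4352 for the controls (2603 higher in DU145), since fewer genes were tested. With the 4 DU145 libraries alone 46 genes were called (41 of the 290), and 1 gene was called alike in both lines. The replicate numbers do not pair the libraries, as same-numbered deviations correlated between -0.042 and 0.014. With a replicate block, which takes degrees of freedom, 11 genes were called in DU145, 833 in PC3, 74 for the difference and 1 alike in both lines, and 804 of the 1350 PC3 genes stayed called. With 1 library left out the counts ranged from 195 to 584 in DU145, 1158 to 1598 in PC3, 1006 to 1650 for the difference, 6248 to 6521 for the controls and 18 to 33 for genes alike in both lines, the lone library being assumed to vary like the other groups. Of the named genes past the test, 28 of 61 in DU145, 27 of 100 in PC3 and 22 of 70 for the difference lost it without at least 1 library. The lists passing ranged from 10 to 17 in DU145, 11 to 20 in PC3 and 14 to 23 for the difference. With an estimated correlation 1 list passed in DU145, 0 in PC3 and 0 for the difference, against 28 for the difference with fry, which does not set a list against other genes. The causes of the other shifts were not tested. Count-based alternatives of the plan (count normalizations, 2 count tests, voom and a count test against a fold) were not run because the table holds TPM, and the unknown depth leaves the precision of low genes open.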

Other observations

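The tests of chance placement and of a few strongly changed genes for chromosomes 20 and 21 were chosen only after the result had been seen, and so were the genes named in this part.

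Targets of growth factor signalling moved in both directions, and the lists that hold them did not pass the camera test. In PC3, 7 of 22 ERK feedback genes fell and 3 rose, with the receptor signalling inhibitor gene SPRY4 falling from 52.1 to 16.0 TPM and the transcription factor gene ETV4 from 177 to 103 TPM (log2 changes -1.64 and -0.77). In DU145, SPRY4 and ETV4 rose by 0.61 and 0.74 and the phosphatase gene DUSP4 from 0.978 to 4.62 TPM (1.51), while IER3 fell from 191 to 80.1 TPM. Of 20 TGF-beta targets 5 rose and 7 fell in PC3. THBS1 and INHBA rose from 249 to 598 TPM and from 101 to 268 TPM, whereas ID3 fell from 90.3 to 37.8 TPM. Of the androgen response and luminal prostate genes 5 of 15 rose and 4 fell in PC3, with STEAP4 rising from 0.925 to 6.96 TPM and HOXB13 falling from 54.5 to 22.9 TPM. Of the NRF2 targets NQO1 fell from 185 to 89.5 TPM in PC3 (-1.04). The lists of macrophage and of fibroblast markers did not pass in either line (camera adjusted p = 0.246 and 0.207 in DU145, 0.116 and 0.545 in PC3).

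A block of neighbouring genes on chromosome 17, listed from 40253422 to 40673503, was near 0 in PC3 with and without TRIB1. In control DU145 against control PC3, STAT3 stood at 142 against 0.140 TPM, STAT5A at 22.5 against 0.066 TPM, STAT5B at 31.2 against 0.393 TPM, KAT2A at 102 against 0.044 TPM, RAB5C at 128 against 0.288 TPM and ATP6V0A1 at 57.3 against 0.887 TPM. CAVIN1 lies in the same block. The next gene, NAGLU, stood at 34.6 against 10.96 TPM.

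Genes of chromosome 20q and chromosome 21 were lower together in DU145 with TRIB1, with a median log2 change of -0.309 over 274 protein-coding genes and -0.336 over 144, against -0.059 over 13996 others, in the first (-0.262 and -0.339) and the second (-0.327 and -0.331) TRIB1 library alike, and 20p was lower by less (-0.119 over 123 genes). Of 13 windows of 10 Mb beyond the bounds of 1000 shuffles of gene positions in the whole genome, 5 lie in these regions, with medians under the lower bound of -0.279 for the most extreme window, which argues against chance placement. A few strongly changed genes are argued against by the 85.9% of 418 genes below 0, where the share of all other genes was 60.3%, although the regions were picked for being low, and GC content by a median of -0.251 relative to genes of like GC. A lower copy number of both arms in the infected DU145 cells could account for the pattern, but no DNA was measured. Every window of at least 10 genes was lower (medians -0.365 to -0.264). This adds little, since the regions were picked for being low and 5 of these 6 windows lay under the lower bound. In PC3 the same regions had medians of -0.222 and -0.134, and 20p -0.21. Like the shift of 20p in DU145, these are not covered by a lower copy number of both arms in DU145 and stay open.

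In PC3, 22 windows of 10 Mb lay beyond such bounds, 18 upward and 4 downward. The highest was chromosome 8 from 50 to 60 Mb, where 20 of 20 genes had a log2 change above 0 (median 0.783), and the lowest chromosome 18 from 40 to 50 Mb (median -0.525). Chromosome 8 from 120 to 130 Mb, which holds TRIB1 by its listed interval, was upward as well (31 of 35 genes above 0, median 0.348). In DU145 that window lay within the bounds. CXCL8 lies in another upward window, chromosome 4 from 70 to 80 Mb (43 of 51 genes above 0, median 0.408), whereas IL6 lies in none. How many of the other rising cytokine genes lie in such windows was not counted. CXCL8 and IL6 therefore do not show how much of the list rise comes from shifted windows. Whether copy number bears on the rise of TRIB1 or of NF-kB cytokine genes in PC3 was not tested.

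The second DU145 TRIB1 library differed from its partner in more genes than the other pairs did, and in every pair most of these were short gene models. Between these libraries 1152 genes differed by more than 2 on the log2 scale, against 711 to 767 in the other groups, and 86.6% of them span under 300 nucleotides, against 15.1% of all tested genes and 82% to 83.3% of such genes in the other groups. Of the 1152, 15 are protein-coding. The median absolute difference of protein-coding genes was 0.135, within the 0.1 to 0.168 of the other groups.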
